A study of Drosophila melanogaster with 4 samples.

How the data were processed

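Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map a trimethylated form of histone H3 (H3K27me3), a modification made by the Polycomb repressive complex PRC2 and found over silenced developmental genes. The material was nuclei from heads of adult Drosophila melanogaster of the wild-type strain Oregon-R, kept in population cages on a 22-day cycle and separated from bodies by sieving, per the labels' protocols. Tissue was fixed with formaldehyde, the chromatin was sheared by sonication and precipitated with an Abcam antibody of lot 3. The series holds 2 ChIP libraries and 2 input libraries, with 1 input for each ChIP library. The labels do not say whether the replicates came from separate collections of flies, so the spread between them may be technical.

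Each ChIP library came with its own list of enriched regions, and a further list was given for the series as a whole. The inputs had no list of their own and entered only through the authors' calling. Reads had been aligned with Bowtie 0.12.7, per the submitters' processing notes. Positions are on FlyBase release 5 of the genome, per the file headers, and are printed 1-based. The region caller, its threshold and its smoothing are not given in the sources used here, nor is it stated whether the whole-series list came from pooled reads or from merged calls. Each region carries a score that the authors deposited. The scale of the score is not given in the sources used here, so it was used only to rank or describe regions within a list. Read numbers per library are unknown from these lists, so no value has an error from sequencing depth. A list of called regions also hides signal below the authors' threshold, and its length grows with depth and with the leniency of the call.

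The list of replicate 2 held 1 region marked as depleted, which was left out of all comparisons. In the whole-series list, 1 start was written in exponent form and was read as 18000000. No list had regions that overlapped one another. The gene table at hand was of release 6, and coordinates were not carried between releases. The assignment of regions to genes, the 22 gene lists fixed for it and the shares of promoters, exons and introns were therefore not analysed here, and regions are named by position. The regions to be named were fixed by rule: the 10 widest stretches covered in both replicates, the widest region of each list, and the 3 regions with the highest score in each list. This took the place of the rule for named genes, which needed an annotation of the same release, so no genes are named. Other positions are marked in the text as chosen after their values were seen.

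Overlap was measured in base pairs, as the share of one replicate's covered length inside the other's and as the Jaccard index (shared length over the length covered in either). It was compared with 1000 random rotations of the regions of replicate 1, each sequence rotated end to end by its own offset, which keeps widths and spacing (one-sided permutation test). A p of 0.001 is the smallest these rotations can give. The p-value concerns the placement of the regions in these libraries and not a difference between conditions. Regions were counted as shared when they touched the other list by at least 1 bp. Shares of regions have exact Clopper-Pearson 95% intervals, which cover counting error only, because neighbouring regions are not independent. For width classes, 200 rotations gave the share expected by chance. A further 200 rotations moved regions only through sequence outside the other regions of the same list, a check added after the first result was seen. On simulated narrow regions placed at random this check gave 10.3% where 6.86% had met the other list, in 10 simulated lists of 4430 regions. It thus overstated chance for regions placed one by one, which was not shown for regions in groups, as in the data. Scores of shared and unshared regions were compared by a two-sided permutation test of the difference in medians (100000 resamples), across regions of 1 library, which are not independent replicates. Values for chromosome arms are means of the 2 replicates with the SD. Differences between arms were taken within each library, and an exact two-sided sign-flip permutation test of 2 such differences cannot give a p below 0.5, so none was run.

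The alternatives fixed before the data were examined were stricter score limits, a minimum width, joining of near regions, larger minimum overlaps, lists cut to equal length, major arms only and each replicate alone. On simulated lists built from the widths of the 4865 regions of replicate 1, the code measured a shared length of 55.5% where 55.6% had been planted with chance overlap included, in 20 simulated lists. It gave p below 0.05 in 3 of 40 lists placed independently. The regions of these lists were placed one by one, without the grouping of regions in the data. The score test, on the same 4865 regions, gave p below 0.05 in 3 of 40 shuffled lists and in 40 of 40 lists with a planted shift of 0.1. The test of gaps did so in 1 of 20 sets with independent gaps and in 20 of 20 with copied ones. Its 100 simulated domains had equal lengths and were not formed by joining 2 lists, as the domains of the data were. The neighbour test placed 1 of 20 random lists of 4809 regions above all its random placements. The comparisons of scores on X and of repeated scores were not tested on simulated data. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.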

Results

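H3K27me3 was mapped in head nuclei of wild-type adult flies by ChIP-seq in 2 replicates, each called against its own input. Replicate 1 gave 4865 enriched regions covering 28.5 Mb, and replicate 2 gave 10330 regions covering 40.9 Mb. The mean covered length was 34.7 Mb ± 8.76 (SD, n = 2). The list of the whole series held 10507 regions and 46.4 Mb. As the lists do not give read numbers, the depth of each library is unknown.

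The first question was where in the genome of adult heads the mark lies. H3K27me3 regions took up most of their length on the 5 major arms, with the highest share on 3R and the lowest on X. On 3R, the arm that carries both Hox gene complexes of Drosophila, 34.4% ± 8.31 (SD, n = 2) of the sequence lay in regions. The share was 31.4% ± 8.88 on 2R, 29.6% ± 5.23 on 2L, 24.4% ± 6.80 on 3L and 22.2% ± 5.54 on X (SD, n = 2 each). On each of these arms the share was higher in replicate 2, the longer list, for example 37.7% against 25.1% on 2R. Arms were therefore also compared within each library. 3R exceeded X by 10.2 percentage points in replicate 1 and by 14.1 in replicate 2, a mean difference of 12.2 ± 2.78 (SD, n = 2). It exceeded 3L by 10.0 ± 1.51 and 2R by 3.00 ± 0.568 points (SD, n = 2). The difference from 2L, 4.77 ± 3.08 points (SD, n = 2), was positive in both replicates but varied the most among the major arms. 3R stayed highest under the alternatives run, but X was not always lowest: with equal numbers of regions taken by score, X covered 20.9% and 3L 19.3% as means of the replicates, and with regions at or above the median score 20.7% and 17.7%.

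**Figure D1:**
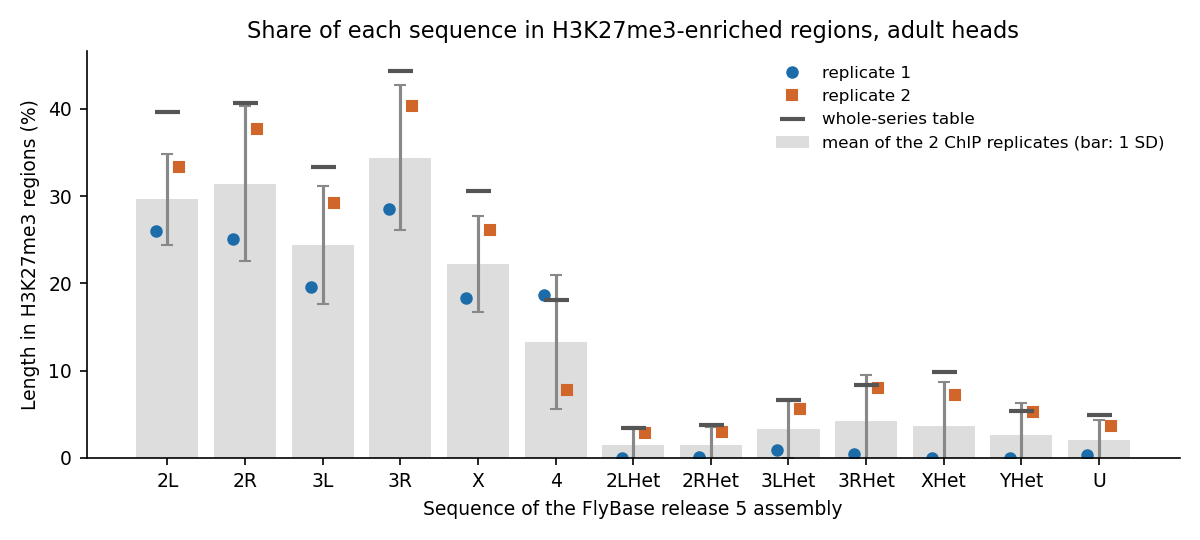
Share of each sequence of the release 5 assembly that lies in H3K27me3-enriched regions (vertical axis, percent), with grey bars for the mean of the 2 ChIP replicates, error bars of 1 SD and points for each list. Arm 3R has the highest mean (34.4%), and on chromosome 4 replicate 1 (18.7%) lies above replicate 2 (7.82%), the reverse of the major arms.

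The small chromosome 4 and the heterochromatic sequences differed from the major arms and between the replicates. On chromosome 4, a chromosome rich in repeats, replicate 1 covered 18.7% with 21 regions and replicate 2 covered 7.82% with 43 regions. The direction was opposite to that on every major arm, and it remained after regions under 5 kb apart were joined (258.0 kb in replicate 1 and 146.6 kb in replicate 2). On the separately assembled heterochromatic sequences and the unplaced sequence U, together 19.3 Mb, replicate 1 had 35 regions (74959 bp) and replicate 2 had 402 regions (848319 bp). These made up 0.263% of the covered length of replicate 1 and 2.08% of that of replicate 2. Replicate 1 had no region on 2LHet, XHet or YHet, where replicate 2 had 6, 8 and 4 regions. Of the length of replicate 2 on these 7 sequences, 4.11% was also covered in replicate 1, and of the length of replicate 1, 46.5% was covered in replicate 2. The Jaccard index there was 3.93%, against 0.390% in rotated lists (p = 0.001, one-sided permutation test). The rotations covered the full length of each sequence, including any part to which no read maps. Such parts would lower the rotated index, and their effect was not tested. The pooled index was uneven over the sequences. By the same test p was 0.001 on 3RHet and on U, and 0.002 on 2RHet, where replicate 1 had 2 regions. The index on 2RHet was 2.66%, just below its highest rotation of 2.67%. On 3LHet the index was 2.82%, below the highest rotation of 7.67% (p = 0.0529, one-sided permutation test).

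The widest unbroken stretches covered in both replicates lay on 3R, 2R and X. Any gap in either list ends a stretch, so the ranking also depends on how the calls were split. A 180 kb region of replicate 1 on 2L, for example, was covered to 97.5% by 8 regions of replicate 2. It gave no stretch among the 10 widest. Of the 10 widest, 6 lay on 3R, 3 on 2R and 1 on X. The widest was 103913 bp long, at 9680999 to 9784911 on 3R, inside a region of 119 kb in replicate 1 and a region of 103975 bp in replicate 2. The next were 99.5 kb at 26514799 to 26614338 and 99.3 kb at 12483843 to 12583138, both on 3R. A stretch of 94.5 kb lay at 7370654 to 7465117 on 2R, followed by 89.8 kb at 16772190 to 16862010 on 2R and 88.1 kb at 3887855 to 3975924 on X. The other 4 were 87.9 kb at 25329565 to 25417426 on 3R, 80.7 kb at 18104501 to 18185174 on 2R, 78.1 kb at 7085972 to 7164028 on 3R and 77.9 kb at 6256077 to 6333972 on 3R. A stretch unbroken in both replicates lies within 1 region of each by definition, unless regions abut. Each of the 10 also lay within 1 region of the whole-series list. In all, 5989 stretches with a median width of 1977 bp were covered in both replicates, of which 30 were at least 50 kb wide.

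As deposited, replicate 1 held more regions of at least 50 kb than replicate 2, although both had nearly the same median width (2152 and 2142 bp). The widest region of replicate 1 spanned 241 kb, at 2649127 to 2890168 on 3R. In replicate 2 it was covered to 96.9% by 10 separate regions, and in the whole-series list to 99.5% by 2 regions. The next 2 were named after their values were seen. The first, 227 kb at 12587207 to 12814232 on 3R, was covered to 96.3% by 11 regions of replicate 2. The other, 180 kb at 11316969 to 11497021 on 2L, was covered to 97.5% by 8 regions of replicate 2 and whole by 1 region of the whole-series list. The widest region of replicate 2 measured 103975 bp, at 9680999 to 9784973 on 3R, and that of the whole-series list 186 kb, at 12624789 to 12810540 on 3R. Regions of at least 50 kb numbered 84 in replicate 1 and held 26.9% of its covered length. There were 35 in replicate 2, with 5.88% of its length, and 97 in the whole-series list, with 18.5%. The 84 wide regions of replicate 1 were covered by replicate 2 to a median of 96.3% (lowest 61.1%) in a median of 5 pieces. When regions under 1000 bp apart were joined, 104 domains of at least 50 kb held 35.8% of the length in replicate 1 and 95 held 18.0% in replicate 2. Joining regions under 5 kb apart, chosen after the data were seen, turned the order of the counts, with 171 domains and 55.0% of the length in replicate 1 and 249 domains and 49.4% in replicate 2.

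**Figure D2:**
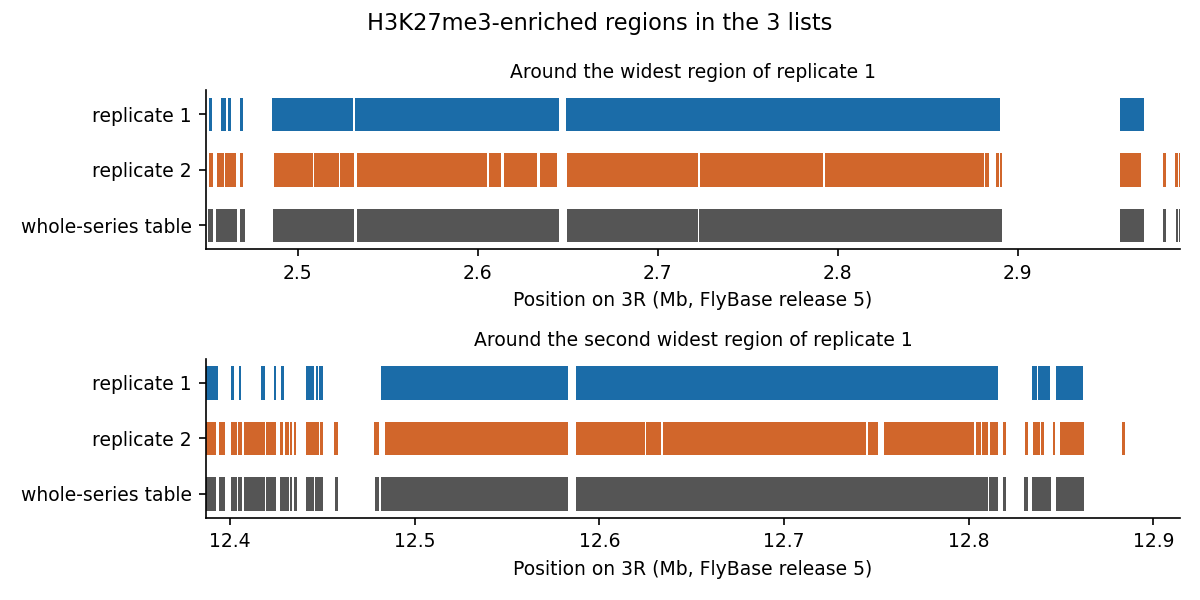
H3K27me3-enriched regions (filled blocks) of replicate 1, replicate 2 and the whole-series list along 3R, around the widest regions of replicate 1; the horizontal axis is the position in Mb on release 5. Blocks of replicate 2 cover the same domains in more pieces, 10 over the 241 kb region of replicate 1 and 11 over the 227 kb region.

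**Figure D3:**
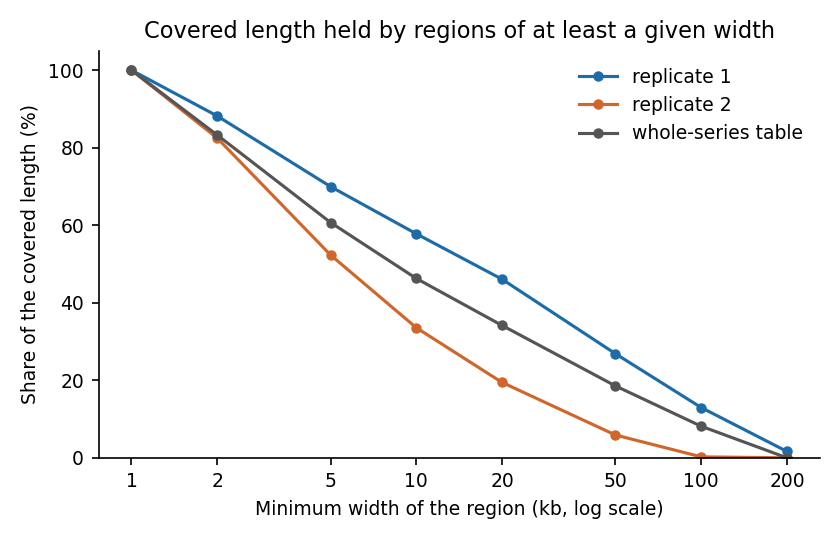
Share of the covered length (vertical axis, percent) held by regions of at least the width on the horizontal axis (kb, log scale), for each list. Regions of at least 50 kb hold 26.9% of the length in replicate 1, 5.88% in replicate 2 and 18.5% in the whole-series list.

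The next comparison asked how far the replicates mark the same sequence. They shared 24.4 Mb, which was 85.6% of the covered length of replicate 1 and 59.6% of that of replicate 2. The Jaccard index was 54.2%, against a mean of 16.3% and a maximum of 23.8% in 1000 rotations (p = 0.001, one-sided permutation test). On the major arms the index ran from 50.4% on 3L to 59.4% on 3R, each above its rotations (p = 0.001 on each arm, one-sided permutation test). On chromosome 4 it was 35.9%, where 37.4% of the length of replicate 1 lay in replicate 2 and 89.5% of the length of replicate 2 lay in replicate 1.

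Wide regions recurred in the other replicate nearly without exception, and narrow ones of replicate 2 mostly did not. Of the regions of replicate 1, 4359 of 4865 (89.6%, 95% interval 88.7% to 90.4%) touched a region of replicate 2. Of those of replicate 2, 4947 of 10330 (47.9%, 95% interval 46.9% to 48.9%) touched a region of replicate 1. After rotation 51.2% and 31.1% did, so the shares of the 2 lists do not stand against a like level of chance. All 84 regions of at least 50 kb in replicate 1 and all 35 in replicate 2 were shared, as were 95.6% and 73.4% of rotated ones. The share of each such region covered by the other replicate had a median of 96.3% in replicate 1 against 26.7% after rotation, and of 100% in replicate 2 against 11.8%. Of the regions of 5 to 20 kb, 746 of 749 in replicate 1 and 1368 of 1560 in replicate 2 were shared, against 63.5% and 39.7% after rotation. Under 2 kb, 1740 of 2125 regions of replicate 1 (81.9%) were shared but 1197 of 4430 regions of replicate 2 (27.02%). Rotation along whole sequences gave 43.8% for these regions of replicate 1. For those of replicate 2 it gave 27.1%, no less than observed. Rotation confined to sequence outside the other regions of replicate 2 gave 10.4%, below the observed share in each of 200 rotations (p = 0.005, one-sided permutation test, the smallest p they can give). For the narrow regions of replicate 2, the comparison with chance thus depended on where the regions were allowed to fall. The confined rotation was added after the first result was seen.

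**Figure D4:**
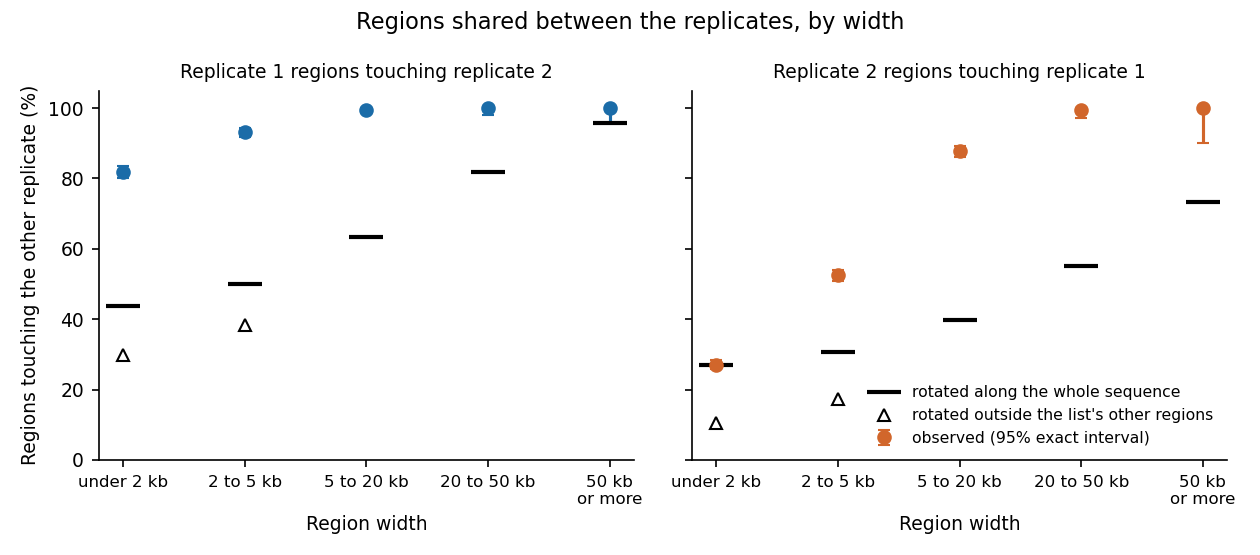
Share of regions touching the other replicate (vertical axis, percent) by region width, with 95% exact intervals, horizontal marks for regions rotated along the whole sequence and triangles for rotation outside the other regions of the same list. In replicate 2, regions under 2 kb (27.02%) lie at the whole-sequence mark (27.1%) and above the triangle (10.4%).

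Shared regions had higher scores than unshared ones within each list. In replicate 1 the median score was 0.69 for 4359 shared and 0.62 for 506 unshared regions, a difference of 0.07. In replicate 2 it was 0.80 for 4947 shared and 0.61 for 5383 unshared regions, a difference of 0.18 (p = 1e-05 in each, two-sided permutation test across regions, the smallest p that 100000 resamples can give). Among the highest-scoring 25% of regions, 96.3% were shared in replicate 1 and 75.1% in replicate 2, and among the lowest-scoring 25%, 82.8% and 32.4%. Shared regions were also wider, with medians of 2314 bp against 1600 bp in replicate 1 and 3270 bp against 1836 bp in replicate 2. Among regions under 2 kb only, the difference in median score was 0.0019 in replicate 1 (p = 0.78, two-sided permutation test) and -0.03 in replicate 2 (p = 4e-05, two-sided permutation test).

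Of the 3 regions with the highest score in each list, 8 of the 9 were under 2 kb wide and 2 of the 6 in the replicates were shared. In replicate 1 the highest score, 2.66, belonged to a region of 1387 bp at 23972910 to 23974296 on 3L that neither other list held. The second, 2.49, belonged to a region of 35.8 kb at 10320087 to 10355865 on 2R, covered to 99.9% in replicate 2 with a score of 2.57, and the third, 2.45, to one of 1566 bp at 112564 to 114129 on U, covered to 62.6% in replicate 2. In replicate 2 the 3 highest were a region of 1615 bp at 21769054 to 21770668 on X (3.07), one of 1478 bp at 7124676 to 7126153 on U (2.98) and one of 1531 bp at 2364249 to 2365779 on 2RHet (2.98). None of these 3 touched replicate 1. The 3 highest of the whole-series list lay at 1656407 to 1658388 on 3RHet (3.83), 9479265 to 9480455 on U (3.63) and 8190557 to 8191968 on U (3.41), and none touched either replicate.

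The whole-series list was set against its replicates to see which calls it carries. It contained 99.99% of the sequence covered in both replicates, together with 85.9% of that covered in replicate 1 alone and 85.8% of that in replicate 2 alone. Of its 46.4 Mb, 52.5% lay in both replicates, 7.60% in replicate 1 only, 30.5% in replicate 2 only and 9.44% in neither. The part in neither amounted to 4.38 Mb. Of its 10507 regions, 1915 (18.2%, 95% interval 17.5% to 19.0%) touched neither replicate, and these had a median width of 1213 bp and a maximum of 3627 bp. Its narrowest region was 1001 bp wide, while both replicates started at 1301 bp. Most of the 1915 regions were therefore narrower than any region of a replicate list, and the 18.2% does not compare the lists at a like minimum width. Its Jaccard index was 59.4% with replicate 1 and 79.0% with replicate 2, against 17.2% and 21.6% in rotated lists (p = 0.001 in each, one-sided permutation test). The whole-series list was given for the series that holds both replicates and is not independent of them. Overlap above rotation was thus fixed in advance, and these p-values give no separate support.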

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

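The overlap of the replicates stayed above rotated lists (p = 0.001, one-sided permutation test) under each alternative run: score limits, minimum widths, joined regions, major arms only and lists of equal length. The Jaccard index ranged from 54.2% to 59.2%. Intervals behind the shares of regions and of the whole-series list take regions as independent, which they are not. The minimum width of 1000 bp removed no region, so it tested nothing, and a minimum of 5000 bp was added after the data were seen. So were joining at 5000 bp for lengths and arms, equal lists for arms, the restriction of scores to regions under 2 kb and the windows at the centromere-side ends of the arms. The share of shared regions moved with the overlap asked for. It fell from 89.6% to 82.3% in replicate 1 and from 47.9% to 40.1% in replicate 2 when 50% of the region's own length had to be covered, and to 45.2% and 21.3% when 50% of both regions had to be. With only regions at or above the median score it was 81.1% in replicate 1. With a minimum of 5000 bp, 1009, 1783 and 1738 regions remained in replicate 1, replicate 2 and the whole-series list, covering 19.9, 21.4 and 28.2 Mb. Joined at 5000 bp, the lists held 1735, 3321 and 3032 regions, covering 33.0, 51.1 and 56.4 Mb. Joined at 1000 bp, the whole-series list held 6523 regions. The part of the whole-series list in neither replicate was 11.9% with regions at or above the median score. The mean share of 2L in regions was 22.2% with that limit, 24.2% with equal lists and 36.4% joined at 5000 bp. In these last cases the counts and lengths changed by construction. The score difference between shared and unshared regions was lost in replicate 1 (0.0019) and turned in replicate 2 (-0.0282) among regions under 2 kb only, where the cause was not tested. Each replicate alone gave 25.9% to 33.3% on 2L, 25.1% to 37.7% on 2R, 19.6% to 29.2% on 3L, 28.5% to 40.3% on 3R, 18.3% to 26.1% on X and 7.82% to 18.7% on 4. Overlap of the replicates cannot be had without either of them. Gene assignments, gene lists and genomic context were not run. No paired analysis was possible because the inputs have no list of their own and the results come from no test between ChIP and input. Unknown read depth limits every comparison of list lengths between the replicates.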

Other observations

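In this part, the tests on the heterochromatic excess and on repeated scores, the windows next to the centromere, the joined domains and the rotation outside wider regions were chosen only after the result was seen, and the test of gap positions was given its present scope, all wide domains, after its result was seen. H3K27me3 regions were sparse at the centromere-side ends of the assembled arms. Distances from the centromere are counted here from that end of the arm sequence. The separately assembled heterochromatic sequences are not in these windows. Whether sequence to which no read maps lowers the values was not tested. In the 1 Mb of each arm next to the centromere, 3.67% ± 4.92 of 2R, 4.35% ± 5.17 of 3L, 7.08% ± 4.10 of X, 10.2% ± 2.30 of 2L and 15.7% ± 4.04 of 3R lay in regions (SD, n = 2 each). The rest of these arms had 32.8%, 25.3%, 22.9%, 30.5% and 35.1%. On 2L, 2R and 3L this was the lowest of all 1 Mb windows in both replicates (of 23, 21 and 24 windows). Counted from the lowest, it had rank 3 in replicate 1 and rank 2 in replicate 2 of 22 windows on X, and rank 5 and rank 2 of 27 on 3R. The values depended on the window. Within 2 Mb of the centromere the means were 8.26% on 2R, 12.1% on 3L, 16.2% on 2L and 16.7% on 3R, still below the rest of these arms (33.8%, 25.5%, 30.9% and 35.8%), but 23.4% on X, above the rest of that arm (22.1%). Within 0.5 Mb they were 2.60% on 2R, 3.85% on 3L, 3.76% on 2L, 7.57% on 3R and 6.33% on X. Coverage did not fall steadily toward the centromere on 3L, where the highest 1 Mb window of replicate 2 (56.8%) started 2 Mb from it.

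Regions lay in groups along the major arms. Neighbours under 5 kb apart made up 64.8% of neighbouring pairs in replicate 1 and 69.8% in replicate 2, against at most 25.7% and 48.3% in 100 random placements of the same widths. The placements moved each region separately, so domains cut into pieces by the calling raise the observed share by themselves. Over all sequences, joining regions under 1000 bp apart turned 4865 regions into 3335 in replicate 1 and 10330 into 6943 in replicate 2. The comparison does not separate such splitting from grouping of distinct regions. Joined across gaps under 5 kb, the widest domain of replicate 1 ran from 2485851 to 2890168 on 3R (404 kb, 3 regions), and the next from 12481635 to 12815693 on 3R (334 kb, 3 regions). In replicate 2 the widest ran from 12478146 to 12819923 on 3R (342 kb, 15 regions), and in the whole-series list from 2485983 to 2891351 on 3R (405 kb, 6 regions). The domain at 1227245 to 1511412 on 2L had rank 4 by width in replicate 1 (284 kb, 25 regions), and its counterpart at 1227697 to 1518939 rank 2 in replicate 2 (291 kb, 39 regions). The single region called depleted in replicate 2, named after its values were seen, lay at 4982140 to 4983876 on 3R, with a score of -0.05.

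Wide domains were interrupted by gaps in both replicates. Inside the regions of at least 50 kb of replicate 1, replicate 2 had 504 gaps with a median width of 548 bp and a maximum of 9.98 kb. The whole-series list covered 94.6% of their 448 kb, but it also covered 84.9% of what replicate 1 alone held in its narrower regions, so this value, set against a bound of 50%, decides nothing about sequence to which no read maps. For a further test, domains were formed by joining the regions of both replicates across gaps under 5 kb. In the 194 domains of at least 50 kb covered by each replicate to 50% or more, gaps of the replicates coincided 1.99 times as much as after rotation within domains (1706 kb against 857 kb, of 4024 kb of gaps in replicate 1 and 3650 kb in replicate 2, p = 0.001, one-sided permutation test). Joining makes any stretch that neither list covers a shared gap, including the spacing between separate regions. The excess thus shows that calls of the replicates coincide inside domains. It cannot decide separately whether gaps have preferred positions. Whether the shared gaps are sites of lower H3K27me3 or of poor mapping stays open, as does a difference in depth or noise between the libraries.

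Regions under 2 kb of replicate 2 met replicate 1 no more than after whole-sequence rotation. Their being kept out of the wide domains may account for this. Outside the wider regions of replicate 2, rotation gave 10.4%, and 27.02% were observed. Rotation does not keep narrow regions beside wider ones, so pieces of domains cut by the calling may raise the observed share by themselves. That rotation overstates chance was shown only for simulated regions placed one by one.

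Replicate 2 had a larger share of its length on heterochromatic and unplaced sequences than replicate 1 (2.08% against 0.263%). Limited to its 4865 highest-scoring regions, replicate 2 kept 2.27% of its length there, but its scores were not higher in shared than in unshared regions under 2 kb (difference -0.0282), so this leaves open a stricter call in replicate 1. Whether the excess was limited to the separately assembled sequences cannot be told apart from a wider one. The ratio of replicate 2 to replicate 1 was larger next to the centromere than on the rest of the arm in 5 of 5 arms within 1 Mb. It ran from 1.38 against 1.28 on 2L to 39.0 against 1.49 on 2R, with 3R near a tie (1.44 against 1.41). Within 0.5 Mb it was larger in the 4 of 4 arms with a ratio, from 2.28 against 1.41 on 3R to 23.1 against 1.28 on 2L. There 2R had no coverage in replicate 1 and 5.20% in replicate 2. The largest ratios rest on little coverage in replicate 1, 0.1835% of the 1 Mb on 2R and 0.3124% of the 0.5 Mb on 2L. Within 2 Mb the ratio was larger in only 3 of 5 arms, and a ratio of single libraries has no spread to set this against. Reads from repeated sequence, a difference between the inputs and a biological difference between the samples stay open and were not tested.

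Narrow regions on X had higher median scores than those on 2L, 2R, 3L and 3R, the only sequences compared. Under 2 kb, the median score on X was 0.71 in replicate 1, where these arms had 0.58 to 0.59, and 0.68 in replicate 2, where they had 0.47 to 0.49. A possible explanation is that X gives fewer reads where males are among the flies, so that a region needs a larger score to be called, which would spare wide regions. The X excess of regions of at least 20 kb was 1.27 times that of the narrow ones in replicate 1 and 0.903 times in replicate 2, and in the whole-series list it was 0.31 against 0.13, values that go against sparing. In the replicates the medians of wide regions on X (1.69 and 1.84) lay within or just above the range of these 4 arms (1.27 to 1.69 and 1.43 to 1.78), whose spread exceeds the excess, so this explanation cannot be told apart from a true difference of X.

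Scores repeated exactly within each list, the most frequent one 71 times in replicate 1. A hypothesis is that the score is the log2 of a product, in which a ratio of small whole numbers is multiplied by a constant for each list. Taken as powers of 2 relative to the most repeated score, 71.4%, 79.6% and 61.2% of the 49 next most repeated scores in replicate 1, replicate 2 and the whole-series list equalled a ratio of whole numbers up to 50 within 1e-07. After random shifts at most 0.0408% did.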
